A study of Mus musculus with 12 samples.

How the data were processed

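Gene expression was measured in cells of the medial telencephalon of CD-1 mouse embryos. Per the labels, siRNAs or an expression plasmid for Dmrta2, together with a vector for nuclear EGFP, were electroporated at embryonic day 11.5, and GFP-positive cells were isolated with a cell sorter 24 hours later, at embryonic day 12.5. The 4 groups were control siRNAs, a first and a second set of siRNAs against Dmrt3 and Dmrta2, and Dmrta2 overexpression, with 3 independent replicates each. The control siRNAs were the only control group, and no array held an empty expression plasmid. Total RNA was prepared with TRIzol and RNeasy columns, and Cy3-labelled cRNA was made from 0.1 ug of RNA with a low-input Agilent kit, per the labels' protocols. Each sample was hybridised to 1 one-colour Agilent mouse array. The 12 arrays lay on 3 slides of 4 arrays, and the slide was the same as the replicate number. Each slide held 1 array of every group, always at the same position, so the position on the slide and the group cannot be told apart.

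The spot intensity used was the processed signal of Agilent Feature Extraction 10.5.1.1, which was background-subtracted and detrended within the array but not normalized between arrays, per the file headers. The series also held a table of log2 values deposited by the authors, whose scale and centring no label stated. Set against the scanner values, these log2 values were the processed signal scaled to the 75th percentile of each array and centred on the median of each probe over the 12 arrays, in the same direction as here. Their correlation with the scanner values so treated was above 0.999 on every array, and the medians of the deposited columns ran from -0.13 to 0.10. The deposited table was used as an alternative. The median spot and local background intensities, as deposited per the file headers, were used for another alternative.

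From the scanner values, control spots and spots carrying an outlier mark were left out (136 to 218 of 43020 spots per array), the 75th percentile of each array's log2 processed signal was subtracted, and spots of 1 probe were averaged. No spot was saturated. The array annotation carried no gene names in the files, so probes were named through their RefSeq accession, without version, in a mouse gene table of assembly GRCm38.p6, while the array annotation used build mm9. For that reason no coordinates are given. Of 39429 probes, 32334 had a RefSeq accession and 26055 were named, for 19751 genes, of which 14481 had 1 probe and 5270 several; 13374 probes had no name here. Probes were kept when well above background on at least 3 of the 12 arrays, and each gene was represented by its probe with the highest mean over all arrays, which left 15369 genes. On each array 67.1% to 72.2% of spots were well above background, and the 75th percentile of the signal ran from 572 to 1142. The number of arrays limits the precision of every value.

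Differences were tested with limma 3.58.1 in R 4.3.3, with lmFit and eBayes over all 12 arrays at 8 residual degrees of freedom and Benjamini-Hochberg adjustment. All tests were two-sided, and the threshold was an adjusted p under 0.05. The comparisons were both siRNA sets averaged, set 1, set 2 and overexpression, each against control siRNAs, and set 2 against set 1. Overexpression against the average of both siRNA sets was added after the data were seen. The standard error (SE) of each log2 difference is limma's moderated one. A gene well above background on none of a group's arrays has only a bound there, and for a gene measured on some arrays of a group their number is given. Its fold is given as "at least", from the brighter group's mean against the mean of, per array, the higher of the probe's own signal and the lowest signal among probes well above background. No fold is given where both groups were below background or the bound was under 1. Dmrt3 and Dmrta2 were also tested with exact permutation tests of the difference of means over all groupings, with Benjamini-Hochberg adjustment over those 10 tests. Every comparison was refitted with the slide as a block, and differences within each slide were computed as values without a test. A slide block leaves each log2 difference as it was and changes its error.

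The main design, the 24 gene lists, the rule for named genes and the alternatives were fixed before the data were examined. The rule took Dmrt3 and Dmrta2, the 12 largest rises and 12 largest falls past the threshold in the siRNA average and in overexpression, and the 5 largest each way in the other comparisons, each with all treated arrays beyond all control arrays. It also took every list member past the threshold and genes that went opposite ways under siRNAs and overexpression. Genes of clone or locus numbers were not named, and up to 2 members of a list with no called member could be given with their values. The lists covered the Dmrt family, ventral and dorsal telencephalic regulators, the cortical hem and choroid plexus, the antihem, the eminentia thalami and diencephalon, the hippocampal field, and targets or components of FGF, Wnt, Sonic hedgehog, BMP and Notch signalling. They also covered neurogenic genes, postmitotic neurons, Cajal-Retzius neurons, S and G2/M phase genes, the interferon, p53 and immediate early responses, and markers of endothelial, erythroid, microglial, mesenchymal and surface ectoderm cells. Of 400 list members, 395 were on the array. Lists were tested with limma's camera at its preset correlation of 0.01 and adjusted over the 24 lists of a comparison. The test was repeated with a correlation estimated from the arrays and with fry, which asks whether the members move on balance 1 way and compares no list with other genes. Each list's members were also adjusted over the list alone.

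Comparisons against the same 3 control arrays share their chance values, so 100 simulations of unchanged groups against those controls were run, and the arrays were also split into other groups of the same sizes. The alternatives were median scaling, quantile normalization, the deposited values, normexp background correction with an offset of 50, no filter and a stricter filter on dim probes, the mean of all probes of a gene, the slide block, fits of the compared groups alone, a variance trend with robust moderation, array weights, a fold of at least 2, an adjusted p under 0.10, and leaving out each array in turn. Normexp was planned on the mean spot signal, which the files did not hold, so its use of the median spot signal was chosen after the data were seen. Its default fit failed on 3 arrays, and normexp with the background's mean and SD from each array's negative control spots was added after the data were seen. A first version of that failed on set 1 replicate 2, where 1 negative control spot was an artefact, and the median and the median absolute deviation replaced them. Also added then were fits with the unnamed probes among the features, the list tests of overexpression against both siRNA sets, and values of partly measured genes with the unmeasured arrays at the lowest signal well above background.

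The code was tested on simulated data with 200 of 15369 genes changed, in 5 runs per comparison. For the siRNA average it recovered 20.6%, 64.5% and 91.5% of genes changed 1.5-fold, 2-fold and 4-fold, with 4.40% of calls false. For overexpression it recovered 11.3%, 54.0% and 93.9%, with 4.68% of calls false. A list of 8 genes shifted by 0.5 on the log2 scale was called in 18 of 20 runs, and in 0 of 20 runs without a shift. The simulated genes varied independently, so these shares do not carry over to correlated lists, such as postmitotic neuron genes (estimated correlation 0.58). Loading and figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.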

Results

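Gene expression in GFP-positive cells of the mouse medial telencephalon was measured 24 hours after electroporation, on 12 one-colour arrays in 4 groups of 3 replicates. The groups received control siRNAs, 1 of 2 siRNA sets against Dmrt3 and Dmrta2 (set 1 and set 2), or an expression plasmid for Dmrta2. Values for 15369 genes were compared. The 75th percentile of the raw signal ran from 572 to 1142 over the arrays, and 67.1% to 72.2% of spots were well above background. Arrays of 1 group correlated at 0.979 to 0.994 across genes and arrays of different groups at 0.976 to 0.991. The first principal component held 26.0% of the variance and followed the slide (R² = 0.96 for slide), and the second held 16.7% and followed the group (R² = 0.811 for group). The number of arrays limits the precision.

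The level of the targeted transcripts asks whether the siRNAs lowered Dmrt3 and Dmrta2, which encode DM-domain transcription factors, and whether the plasmid raised Dmrta2. In the arrays of both siRNA sets Dmrt3 stood at 53.4% of its level under control siRNAs (a log2 difference of -0.91 ± 0.26, SE, n = 6 against 3), and all 6 siRNA arrays lay below all 3 controls. Dmrta2 stood at 72.6% of control in the same arrays (-0.46 ± 0.14). Set 1 alone gave 49.4% for Dmrt3 and 65.3% for Dmrta2, and set 2 alone 57.6% and 80.6%, with 1 of 3 set 2 arrays below all controls for Dmrta2. In the arrays labelled Dmrta2 overexpression, the Dmrta2 probe stood at 70.8% of control, with all 3 arrays below all 3 controls (-0.50 ± 0.16, n = 3 against 3), and Dmrt3 differed by -0.07 ± 0.30. Only 1 probe could be named as Dmrta2, and its position relative to the sequence in the plasmid is not known, so this probe may check nothing about the plasmid.

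Exact two-sided permutation tests over both siRNA sets gave p = 0.0238 for Dmrt3 and p = 0.0476 for Dmrta2, over 84 groupings whose smallest p is 0.0119. Both became 0.143 after adjustment over 10 such tests. Groups of 3 against 3 cannot give an exact p below 0.1, the value reached by set 1 for both genes, by set 2 for Dmrt3 and by overexpression for Dmrta2, while set 2 gave an exact p of 0.3 for Dmrta2. Over all genes, limma's adjusted p was 0.162 for Dmrt3 and 0.204 for Dmrta2, so neither passed the threshold. With the slide as a block these were 0.0284 and 0.112, and both were 0.0167 adjusted over the list alone, the 8 genes of the Dmrt family, where Dmrtb1 (0.62 ± 0.16) and Dmrtc1a, well above background on none of the control arrays, were higher. Within slides 1, 2 and 3 the difference for Dmrt3 was -1.03, -0.41 and -1.27, and for Dmrta2 -0.45, -0.23 and -0.71. The Dmrt family list did not pass in any comparison (lowest adjusted p = 0.314).

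**Figure D1:**
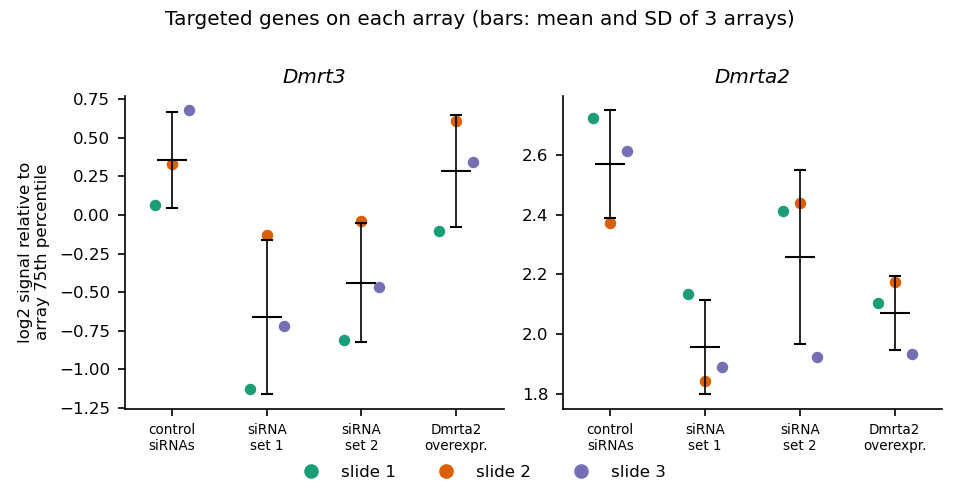
Log2 signal of Dmrt3 and Dmrta2 relative to the 75th percentile of each array, per array and slide in the 4 groups, with the mean and SD of each group (n = 3). All 6 siRNA arrays lie below all 3 control arrays for Dmrt3, while the arrays labelled overexpression do not lie above the controls for Dmrta2 (-0.50 on the log2 scale).

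Comparing both siRNA sets with control siRNAs asks which transcripts respond to lowered Dmrt3 and Dmrta2. Tox, an HMG-box nuclear protein, rose 8.22-fold (3.04 ± 0.37 on the log2 scale, SE, n = 6 against 3), Tacr3, the neurokinin 3 receptor, rose 5.50-fold (2.46 ± 0.28), and Emilin2, an extracellular matrix glycoprotein, rose 3.33-fold (1.73 ± 0.19). The transcription factor genes Olig3 (3.59 ± 0.61) and Neurod4 (1.96 ± 0.32) also rose, from levels measured on 1 of 3 control arrays to levels measured on all siRNA arrays, and with the other controls at the lowest signal well above background the differences were 2.38 and 1.24. Map7, a microtubule-binding protein, rose at least 1.70-fold from below background. Edn2, a secreted endothelin, fell by 1.24 ± 0.16, Apobec1, a cytidine deaminase, by 1.18 ± 0.17, the decapping enzyme gene Dcp2 by 0.82 ± 0.10, and Slc24a4, a calcium exchanger of the cell membrane, by 0.81 ± 0.12. Ednra, a receptor for endothelins, rose by 1.75 ± 0.32 and was measured on 1 control array.

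In all, 103 genes changed, 86 higher and 17 lower (limma, adjusted p under 0.05), and 1857 had an unadjusted p under 0.05 against 768 expected by chance. The adjusted p was 0.0092 for Tox, 0.00778 for Tacr3, 0.00662 for Emilin2, 0.0092 for Dcp2 and 0.011 for Edn2. Within slides 1, 2 and 3 Tox differed by 2.74, 2.49 and 3.89, Tacr3 by 2.22, 3.01 and 2.15, and Edn2 by -1.15, -1.08 and -1.49. With the slide as a block 233 genes passed, 101 of them among the 103. Leaving out 1 array gave 17 genes without control replicate 1, 41 without control replicate 3, 30 and 34 without set 1 replicates 2 and 3, 33, 55 and 30 without set 2 replicates 1, 2 and 3, and 45 without either overexpression replicate 1 or 3. Tox, Tacr3, Emilin2, Eda2r and Map7 passed in all 12 such fits, Olig3 in 3 (highest adjusted p 0.162), Neurod4 in 4, and Elovl7, which fell by 1.49 ± 0.27 with all arrays, in none.

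**Figure D2:**
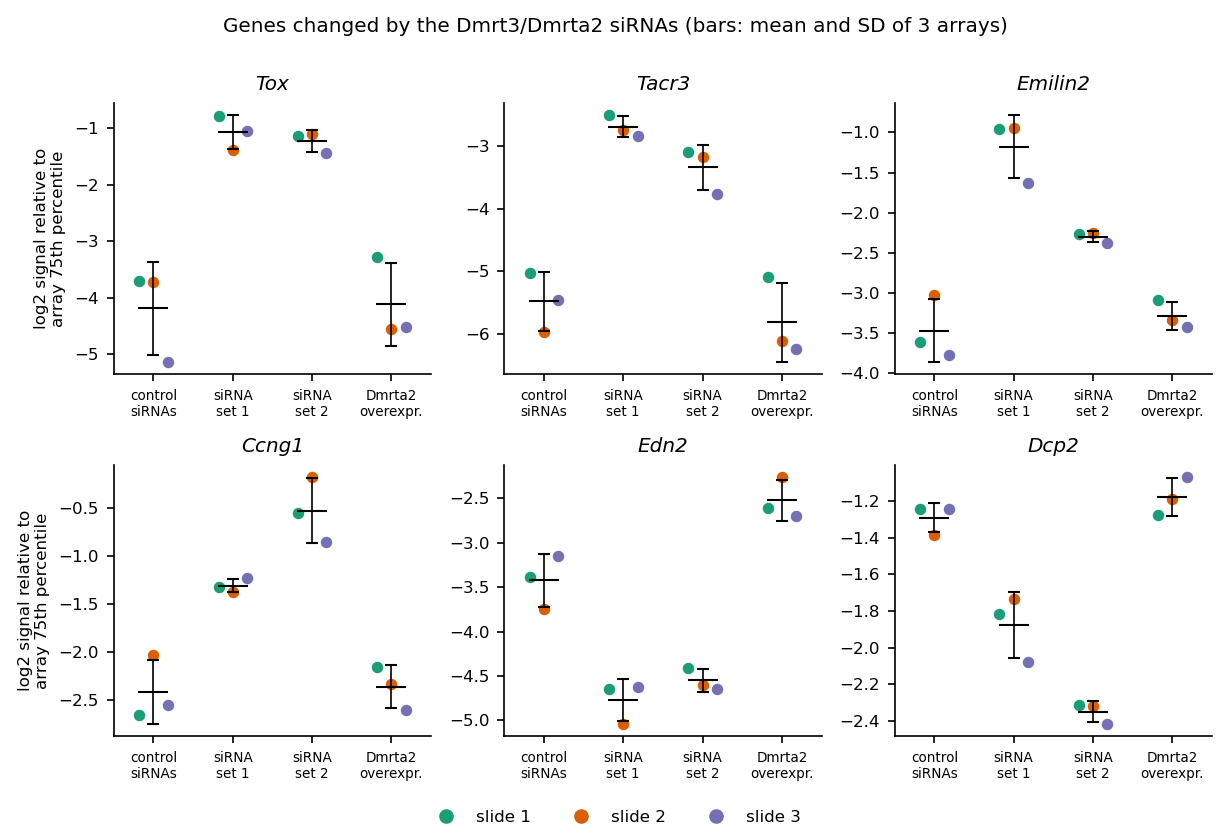
Log2 signal of Tox, Tacr3, Emilin2, Ccng1, Edn2 and Dcp2 relative to the 75th percentile of each array, per array and slide in the 4 groups, with the mean and SD of each group (n = 3). The first 4 genes rose (Tox by 3.04 and Ccng1 by 1.50 on the log2 scale over both siRNA sets) and the last 2 fell (Edn2 by 1.24 and Dcp2 by 0.82).

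Among the fixed lists, the p53 response rose under the siRNAs, with a median of 0.31 over 18 members (camera adjusted p = 0.00259, and adjusted p = 0.269 with an estimated correlation). Of its members, Ccng1, a cyclin induced by p53, rose 2.83-fold (1.50 ± 0.18). Eda2r, a p53-induced receptor, also passed (adjusted p = 0.00662), but was well above background on 3 of 6 siRNA arrays and on none of the controls. With the unmeasured arrays at the lowest signal well above background, the Eda2r difference was 0.0678. The other 16 did not pass over all genes, and 4 members passed adjusted over the list alone. S and G2/M phase genes fell as a list, with a median of -0.29 and 25 of 28 members negative (adjusted p = 2.62e-06, and 0.644 with an estimated correlation), although no member passed on its own. Their medians within slides 1, 2 and 3 were -0.43, 0.04 and -0.52. Values for its members were -0.47 ± 0.13 for E2f1, a transcription factor of S-phase entry, and -0.54 ± 0.19 for Cdt1, a replication licensing factor. The slide medians of the p53 list were 0.24, 0.50 and 0.10, and with the slide as a block the adjusted p was 0.0078 for p53 and 8.12e-05 for S and G2/M genes.

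Regulators of the ventral telencephalon rose as a list (median 0.17, adjusted p = 0.0163, and 0.644 with an estimated correlation), with no member past the threshold over all genes and 4 of 19, Dlx1, Isl1, Olig2 and Etv1, higher adjusted over the list alone. Isl1 and Olig2 encode transcription factors, of which Olig2 stood at 0.96 ± 0.20 (adjusted p = 0.0674) and Isl1 (0.0715) was well above background on none of the control arrays. The median of the 11 members well above background on all arrays was -0.01. The list did not pass without set 1 replicate 1 (adjusted p = 0.116) or control replicate 2 (0.109). Slide medians were 0.56, 0.19 and 0.16, and the blocked adjusted p was 0.0434. The BMP response fell (median -0.22, adjusted p = 0.043, and 0.269 with an estimated correlation), at -0.19, -0.17 and -0.22 within slides, with a blocked adjusted p of 0.0367. It did not pass without set 1 replicate 1 (0.116), set 1 replicate 2 (0.0603) or control replicate 3 (0.179). Dorsal telencephalic regulators did not pass in any comparison (lowest adjusted p = 0.0735), and Pax6, a member, stood at 1.06 ± 0.27 (adjusted p = 0.118, and 0.038 with the slide as a block).

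Markers of other cell types moved with the siRNA groups. The microglia and macrophage list rose, with a median of 1.16 over 12 members and of 0.88 over the 8 well above background on all arrays (adjusted p = 2.65e-10, and 0.189 with an estimated correlation). Tyrobp, an immune signalling adaptor, rose by 1.53 ± 0.22, Cx3cr1, the fractalkine receptor, by 1.20 ± 0.18, Aif1 by 1.13 ± 0.19 and C1qa, a complement component, by 1.79 ± 0.32 from a level measured on 1 control array. The other 8 did not pass over all genes, and 7 passed adjusted over the list alone. Slide medians were 1.66, 1.09 and 0.63, and the blocked adjusted p was 1.33e-07. Erythroid genes rose (median 0.66, adjusted p = 0.0202, and 0.65 with an estimated correlation; 1.68, 0.33 and 0.62 within slides; 0.0367 with the block), but not without set 1 replicate 1 (0.13) or control replicate 2 (0.103).

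Each set alone asks whether the response is shared by different siRNAs. Set 1 changed 36 genes, 25 higher and 11 lower, and set 2 changed 157, 66.9% of them higher and 52 lower (limma, n = 3 against 3). Set 1 raised Tox (3.12 ± 0.42), Tacr3 (2.78 ± 0.33), Olig3 (5.06 ± 0.71) and Neurod4 (2.48 ± 0.37), these last measured on 1 control array each (3.86 and 1.76 with the other controls at that lowest signal), and Map7 (at least 2.54-fold), and lowered Apobec1 (-1.50) and Edn2 (-1.35). Set 2 raised Tox (2.96 ± 0.42), Poln, a DNA polymerase (2.40 ± 0.22), and Ccng1 (1.89 ± 0.21), and lowered Elovl7 (-1.73) and Tal2, a basic helix-loop-helix factor (-1.56). Of 16 genes changed in the same direction by both sets, 14 rose, among them Tox, Tacr3 and Emilin2, and Slc24a4 and Edn2 fell. Eda2r counts among the 14 but was well above background on 1 of 3 set 1 arrays and on none of the controls, and its set 1 difference was -0.07 with the unmeasured arrays at that lowest signal.

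For lists sharing no samples, 0.171 genes higher in both and 0.0372 lower in both would be due. The 100 simulations of unchanged groups with shared simulated controls gave 0 in the same direction. They called a mean of 0.04 genes in set 1 and 0.06 in set 2. Their 0 was thus due in advance and cannot gauge the overlap of lists that hold changed genes. The log2 changes of both sets correlated across genes at 0.589 (simulated 0.501, highest 0.534), with a covariance of 0.0743 against 0.0413. Genes are not independent replicates, the 3 controls could not be split, and part of the excess may come from them. With the slide as a block, set 1 changed 114 genes, set 2 changed 365, and 54 changed in the same direction. Set 1 gave 4 genes without its replicate 2, 8 without its replicate 3, 9 without its replicate 1, 10 and 13 without control replicates 1 and 3, 12 without set 2 replicate 3, 20 without overexpression replicate 3, and 83 without control replicate 2. Set 2 gave 10, 34 and 23 without its replicates 1, 2 and 3, 30, 43 and 31 without control replicates 1, 2 and 3, 50 without set 1 replicate 3, 25 and 30 without overexpression replicates 1 and 3, and 104 without overexpression replicate 2. The 16 shared genes became 2 without set 2 replicate 1 or set 1 replicate 2, 3 without control replicate 1 or set 1 replicate 3, 4 without control replicate 3 or set 2 replicate 3, 6 without set 1 replicate 1, 7 and 8 without overexpression replicates 3 and 1, and 8 without set 2 replicate 2.

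In set 2 the p53 list rose (median 0.44, adjusted p = 7.48e-05, and 0.117 with an estimated correlation). Ccng1, Bbc3, a promoter of apoptosis (0.94 ± 0.14), Phlda3 (1.25 ± 0.20) and Eda2r (at least 1.15-fold, measured on 2 of 3 arrays) rose, and 6 members were higher and 1 lower adjusted over the list alone. In set 1 the p53 list did not pass (adjusted p over the 24 lists 0.162 or more). The microglia list rose in set 2 (median 1.53, adjusted p = 1.56e-10, and 0.117 with an estimated correlation; 1.88, 1.38 and 0.98 within slides), with 5 of 12 members past the threshold, and in set 1 (median 0.72, adjusted p = 2.35e-06, and 0.491 with an estimated correlation; 1.07, 0.58 and 0.18 within slides), with 0 past it over all genes and 6 adjusted over the list alone. S and G2/M genes fell in both sets (set 1 adjusted p = 5.68e-06, and 0.491 with an estimated correlation; set 2 1.43e-04, and 0.711), and in set 2 not without its replicate 1 (0.127). Their slide medians were -0.29, -0.23 and -0.50 in set 1 and -0.57, 0.26 and -0.52 in set 2. With the slide as a block the adjusted p was 4.35e-04 for the p53 list of set 2, whose slide medians were 0.36, 0.82 and 0.26, and 8.82e-08 and 9.02e-05 for the microglia list in set 2 and set 1.

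Of the 11 lists past the threshold in set 1 and the 8 in set 2, none held with an estimated correlation (adjusted p of 0.491 to 0.759 in set 1 and 0.117 to 0.721 in set 2). In set 1, ventral regulators (adjusted p = 0.00136, 6 of 19 members higher adjusted over the list alone, with a median of 0.38 over all members and 0.02 over the 11 well above background on all arrays), Wnt targets (0.00304), the mesenchyme (0.00758), hippocampal field (0.0174), neurogenic (0.0188) and hem (0.0282) lists, and Cajal-Retzius (0.0394), erythroid (0.0394) and postmitotic neuron genes (0.0473) also rose. Mesenchymal markers had slide medians of 2.71, 0.10 and 0.48 there, and the list did not pass without set 1 replicate 1 (0.289). In set 2, interferon genes (0.00372), erythroid (0.027) and endothelial markers (0.037) rose, and BMP (0.027) and surface ectoderm genes (0.0498) fell. Interferon genes had slide medians of 2.56, 0.36 and 0.14, and the list did not pass without set 2 replicate 1 (0.287). Slide medians of set 1 changed sign for neurogenic (-0.01 on slide 2), postmitotic (-0.34) and erythroid genes (-0.26). Single arrays also ended set 1 calls of the hem (adjusted p = 0.371 without control replicate 1), neurogenic (0.422 without control replicate 3), postmitotic (0.898 without control replicate 3), Cajal-Retzius (0.307 without control replicate 1), hippocampal (0.277 without set 1 replicate 2) and erythroid lists (0.815 without set 1 replicate 1). In set 2 they ended those of the BMP (0.129 without control replicate 3), endothelial (0.402 without set 2 replicate 3), erythroid (0.135 without control replicate 2) and surface ectoderm lists (0.189 without control replicate 3). With the slide as a block, the hem (0.0621), postmitotic (0.0664), Cajal-Retzius (0.104) and erythroid (0.0621) lists of set 1 and the surface ectoderm list of set 2 (0.0534) did not pass.

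Set 2 against set 1, the test of the difference itself, changed 12 genes, 5 higher and 7 lower in set 2. Poln was higher in set 2 by 1.91 ± 0.22 and Sesn3, a stress-induced sestrin, lower by -1.16 ± 0.13, while Ccng1 (0.78 ± 0.21, adjusted p = 0.218), Olig3 (-2.95 ± 0.71, 0.157) and Tyrobp (0.94 ± 0.26, 0.236) did not pass. Within slides Poln differed by 1.53, 2.29 and 1.90 and Sesn3 by -1.03, -1.28 and -1.15. Blocking on the slide gave 33 genes. The count was 12 without control replicate 2, 8 without control replicate 3, 7 without overexpression replicate 2, 4 without control replicate 1, 1 without set 1 replicate 1, and 0 without any 1 of the other 7 arrays (limma, 1108 to 1534 genes at an unadjusted p under 0.05 in those fits).

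Comparing the arrays labelled Dmrta2 overexpression with control siRNAs asks which transcripts differ where the plasmid was given. Lamp5, a neuronal membrane protein of the LAMP family, rose at least 10-fold from below background in all 3 controls. Ecel1, an endopeptidase of neurons, rose 12.6-fold (3.66 ± 0.38, SE, n = 3 against 3), Fam20a, a pseudokinase of the secretory pathway, 6.04-fold (2.60 ± 0.30), and Lrfn2, a synaptic adhesion protein, by 2.46 ± 0.37. Cilp, a cartilage matrix protein, rose at least 7.54-fold, the epithelial keratin gene Krt8 at least 3.58-fold, and Ptgir, the prostacyclin receptor, at least 2.39-fold. Ebf1, a transcription factor of early neurons, rose 2.53-fold (1.34 ± 0.18), and Cacna2d2, a calcium channel subunit, 3.32-fold (1.73 ± 0.25; 2.07 on its other probe).

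In this comparison 42 genes rose and 0 fell with limma. At an unadjusted p under 0.05, 575 genes were higher and 107 lower, 682 in all against 768 expected by chance. With the slide as a block, the limma count at that unadjusted p was 1029, above the 768. The adjusted p was 0.000235 for Lamp5, 0.00249 for Ecel1, 0.0036 for Fam20a, 0.0121 for Ebf1 and 0.0186 for Cacna2d2. Within slides 1, 2 and 3 Ecel1 differed by 4.05, 3.04 and 3.89, Fam20a by 2.93, 2.19 and 2.67, and Ebf1 by 1.63, 0.87 and 1.52. Blocking on the slide gave 51 genes, 35 of them among the 42. The count was 18 without overexpression replicate 1, 19 (1 lower) without overexpression replicate 3, and 23 without control replicate 1. Vstm2l (2.39 ± 0.39, adjusted p = 0.0442) and Padi2 (at least 4.54-fold, 0.0499) each passed in 3 of 12 fits that left out 1 array and did not pass with the block (0.0748 and 0.0714). The controls received siRNAs and not a plasmid without Dmrta2, so the type of nucleic acid differs between these groups.

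**Figure D3:**
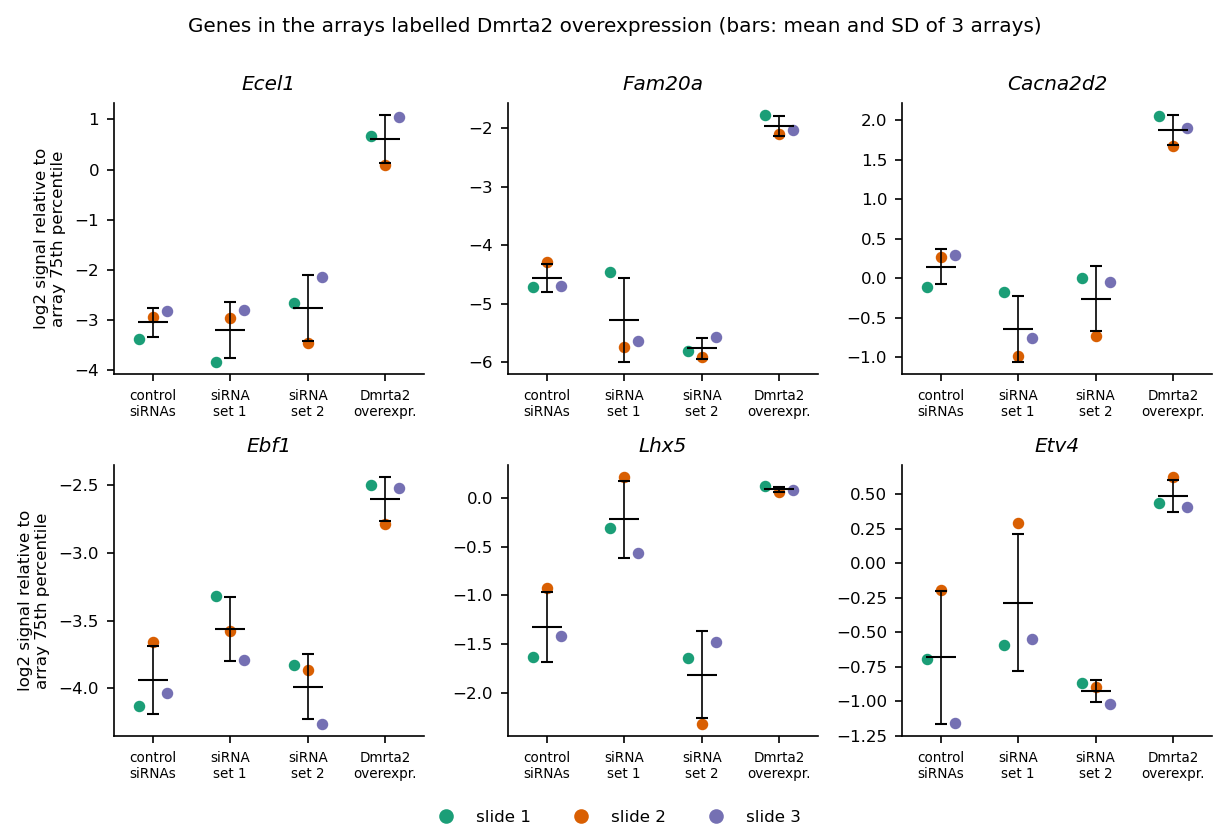
Log2 signal of Ecel1, Fam20a, Cacna2d2, Ebf1, Lhx5 and Etv4 relative to the 75th percentile of each array, per array and slide in the 4 groups, with the mean and SD of each group (n = 3). Ecel1, Fam20a, Cacna2d2 and Ebf1 rose in the arrays labelled overexpression (3.66, 2.60, 1.73 and 1.34 on the log2 scale), while Lhx5 (1.41) and Etv4 (1.17) did not pass the threshold.

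Lists of medial and rostral telencephalic signalling rose in the arrays labelled overexpression. The cortical hem and choroid plexus list had a median of 0.57, with 23 of 25 members positive (camera adjusted p = 4.76e-12, and 0.0362 with an estimated correlation). None of its members passed over all genes, and Msx1, a BMP target in the dorsal midline, was higher adjusted over the list alone (0.72 ± 0.15). The rostral FGF list had a median of 0.53, with 11 of 12 positive (1.05e-06, and 0.0362 with an estimated correlation). None passed over all genes, and 3 did adjusted over the list alone, the FGF-induced Etv4 (1.17 ± 0.27), Etv5 (1.14 ± 0.33) and Spry1 (0.57 ± 0.17). Cajal-Retzius genes, of neurons that arise in part at the hem, had a median of 0.52, with 8 of 10 positive (1.44e-08, and 0.0362 with an estimated correlation). Cacna2d2 rose, 9 did not pass, and 5 were higher adjusted over the list alone, with Lhx5 at 1.41 ± 0.26 and Trp73 at 0.91 ± 0.25. Slide medians were 0.92, 0.36 and 0.40 for the hem list, 0.48, 0.51 and 0.54 for FGF and 0.92, 0.20 and 0.79 for Cajal-Retzius genes, and the blocked adjusted p values were 2.77e-11, 1.24e-07 and 9.60e-07.

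The microglia list rose in the same arrays (median 1.65, and 1.15 over the 8 members well above background on all arrays; adjusted p = 4.64e-18, and 0.0362 with an estimated correlation). Tyrobp (1.95 ± 0.26), Aif1 (1.69 ± 0.22), Cx3cr1 (1.60 ± 0.21) and C1qc (1.79 ± 0.30) rose, the other 8 did not pass, and 7 were higher adjusted over the list alone. Slide medians were 1.71, 1.43 and 0.80, and the blocked adjusted p was 1.16e-12, though C1qc alone did not pass with the block (0.0508). Over the 4 comparisons against control siRNAs, 39 of 96 list tests passed, and the 4 that held with an estimated correlation were these hem, FGF, Cajal-Retzius and microglia lists of the overexpression arrays. At the preset correlation all 4 also passed in each fit that left out 1 array, and the form with an estimated correlation was not refitted there.

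A further 10 lists passed in the overexpression arrays, though not with an estimated correlation. Wnt targets (median 0.44, adjusted p = 7.16e-05, and 0.0713 with an estimated correlation), p53 genes (0.18, 4.57e-04, and 0.0713), surface ectoderm genes including Krt8 (0.44, 0.00147, and 0.0713) and the BMP response (0.37, 0.0129, and 0.0713) rose. So did erythroid (1.16, 7.53e-05, and 0.172), interferon (0.40, 0.00513, and 0.444), mesenchymal (0.35, 0.0129, and 0.393) and endothelial markers (0.45, 0.0167, and 0.393) and ventral regulators (0.15, 0.0351, and 0.393), and neurogenic genes fell (-0.12, 0.0489, and 0.444). Their slide medians kept their sign except for interferon genes (0.75, -0.45 and 1.29) and neurogenic genes (-0.04, -0.53 and 0.10), and neurogenic genes did not pass with the block (0.0503). The median of the 5 surface ectoderm members well above background on all arrays was -0.08. Leaving out single arrays ended several of these calls, such as surface ectoderm without control replicate 2 (0.054), BMP without control replicate 2 (0.243) or overexpression replicate 2 (0.155), interferon without overexpression replicate 3 (0.257), mesenchyme without overexpression replicate 1 (0.155), endothelial (0.403) and ventral lists (0.4) without control replicate 2, and neurogenic genes without control replicate 2 (0.985, with a median of 0.08). Antihem (lowest adjusted p over the comparisons 0.668), eminentia thalami (0.124), Sonic hedgehog (0.198), Notch (0.606) and immediate early genes (0.302) did not pass in any comparison. In 17 of the 96 tests a list's median, mean and test differed in sign, none of them past the threshold.

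**Figure D4:**
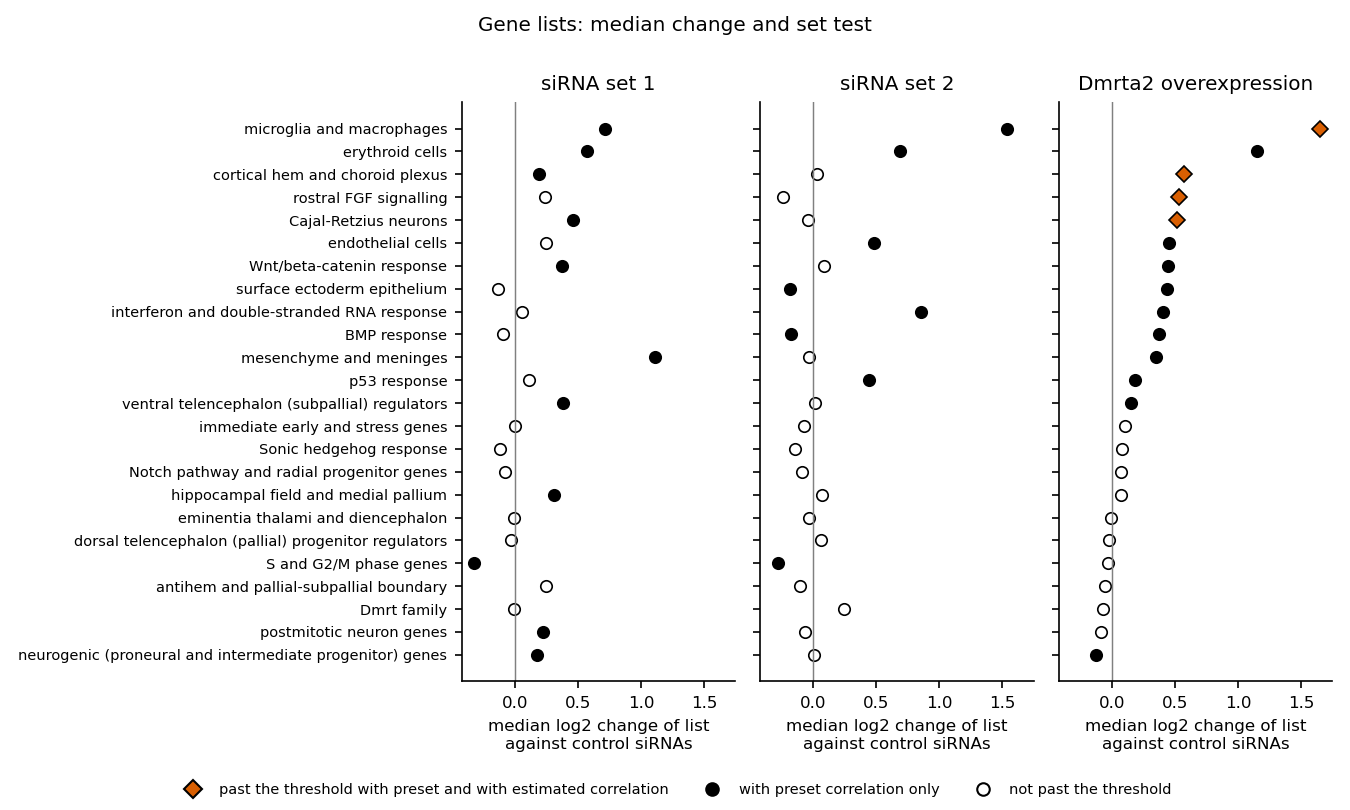
Median log2 difference from control siRNAs of each gene list in set 1, set 2 and overexpression, with diamonds for lists past the threshold also with an estimated correlation, filled circles for lists past it with the preset correlation alone and open circles for others. The hem, FGF, Cajal-Retzius and microglia lists of overexpression (medians 0.57, 0.53, 0.52 and 1.65) hold in both forms of the test.

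Genes that went opposite ways ask whether loss and gain of Dmrt function mirror each other. With limma, 0 genes changed in opposite directions in the siRNA average and the overexpression arrays. Independent lists would give 0.0465 genes lower under siRNAs and higher in overexpression, and 0 the other way, as none fell in overexpression. The 0 was thus nearly due in advance and does not speak against mirrored changes. Past the adjusted threshold there was 1 without set 1 replicate 1. At an unadjusted p under 0.05 there were 53, where 35.5 would be due for independent lists. Simulated unchanged groups with shared simulated controls gave 1.26 (highest 4). In the same direction 5 genes rose in both, Aif1, Cx3cr1, Tyrobp, Vav1, a guanine exchange factor of blood cells, and Cyth4 (0.235 due for independent lists, 0.01 in the simulations), 3 of them microglia list members. No gene was made to change in the simulations, so neither simulated value can gauge the overlap of lists that hold changed genes. The log2 changes correlated across genes at 0.363 (simulated 0.576) with a covariance of 0.0371 against 0.0410 in the simulations. The simulated noise held the slide variance, which cancels in real differences because each slide held every group. Set side by side, the covariances therefore cannot tell whether changes are shared or mirrored beyond the shared controls.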

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

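The tests of explanations for the microglia markers, the p53 response genes and the Dmrta2 probe were chosen after the result was seen, while the splits of the arrays and the test of set 2 against set 1 were planned.

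Some transcripts differed between the siRNA sets in the test of set 2 against set 1 itself, which changed 12 genes. Those higher in set 2 included Poln (1.91 on the log2 scale), Tor1aip2 (1.16), Klhdc9 (0.94) and the peptide deformylase gene Pdf (0.69), and those lower in set 2 included Slc7a10, an amino acid transporter (-1.44), Gprc5c (-1.28), Rcan2, an inhibitor of calcineurin (-1.18), Sesn3 (-1.16) and Emilin3 (-1.13). Other probes for Tor1aip2 gave 0.05 and 0.67, and those for Gprc5c -0.76, -0.77 and -1.17. The 10 splits of these 6 arrays are too few for a share under 0.05, and the real split gave 12 genes, the highest other 0. Blocking on the slide gave 33 genes. Leaving out set 1 replicate 1 gave 1 gene, control replicate 1 gave 4, overexpression replicate 2 gave 7 and control replicate 3 gave 8, and leaving out any of set 1 replicates 2 and 3, set 2 replicates 1, 2 and 3 or overexpression replicates 1 and 3 gave 0 with limma, against 1108 to 1534 at an unadjusted p under 0.05.

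Signal that followed the groups also lay in probes without a gene name, which the comparisons of genes do not use. With limma over 23700 features, 8331 of them unnamed, 18 unnamed probes passed in the siRNA average, 10 in set 1, 20 in set 2, 6 in overexpression and 68 in overexpression against both siRNA sets.

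Microglia and macrophage markers rose in set 2 and in the arrays labelled overexpression, with list medians of 1.53 (camera adjusted p = 1.56e-10, and 0.117 with an estimated correlation) and 1.65 (4.64e-18, and 0.0362), and also in set 1 (0.72, 2.35e-06, and 0.491). A lower share of the main cell type would raise markers of every other type alike. The microglia median instead exceeded that of mesenchyme and meninges by 1.56 in set 2 and 1.30 in overexpression (member SD 0.664 and 0.889). It exceeded that of endothelial markers by 1.05 and 1.20 (0.624 and 0.755), and that of erythroid markers by 0.846 and 0.493 (0.651 and 0.832). Over members well above background on all arrays, microglia and erythroid medians were 1.21 and 0.50 in set 2 but 1.15 and 1.02 in overexpression. In set 1 the mesenchyme median was 1.12, above that of microglia (slide medians 2.71, 0.10 and 0.48). The lowest within-slide microglia median was 0.801, in overexpression. The list was taken up for its rise over the same slides, so this value cannot test a slide batch. Each slide held every group, so a shift shared by a slide's arrays cancels in these differences. Microglia or macrophages carried into the sort stay open, since the 10 of 12 markers positive in overexpression and 11 in set 2 restate the rise of the list and lend it no weight, and the gate on GFP was there to remove cells without the vector. Of the 12 markers 8 lay well above background on all control arrays and 0 were in another list, and among them Tyrobp, Aif1, Cx3cr1 and C1qc rose in overexpression while Ptprc (0.16 ± 0.16) and Csf1r (-0.04 ± 0.55), the brightest probe at 1.92 relative to the 75th percentile in controls, did not pass. A change within microglia that carried GFP, by uptake of labelled cells or otherwise, and an effect of Dmrt3 and Dmrta2 on these cells stay open, as untested.

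The p53 response genes Ccng1, Bbc3 and Phlda3 rose in set 2, with a lowest within-slide median of 0.916. They were chosen for their calls over the same slides, so this value restates the choice and cannot test a slide batch. These 3 genes were lower in overexpression than in set 2 on each slide (-0.911, -1.11 and -0.625, with a mean of -0.882), while the microglia list rose in both. Their choice for calls in set 2 favours such a difference, so it cannot decide whether the cells behind the microglia markers raised them. Those cells stay open, and the whole p53 list rose in overexpression too (median 0.18, camera adjusted p = 4.57e-04, and 0.0713 with an estimated correlation) and did not pass against both siRNA sets (-0.04, 0.348). An effect of set 2 alone stays open, because the median of the 3 genes in set 1 (0.34, 0.606 and 0.307, with a mean of 0.418) rests on the control arrays that also entered their choice, and the p53 list did not pass in set 1 (adjusted p = 0.162). A response to lower Dmrt3 and Dmrta2, which the design names, and a toxicity that both sets share more than the control siRNAs may each account for the rise, and both stay untested.

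The Dmrta2 probe was not higher in the arrays labelled overexpression, at -0.499 against control siRNAs. Unchanged control RNA on these arrays is argued against by 38 genes outside the microglia list past the threshold. With unmeasured arrays at the lowest signal well above background, 8 of them were at least 4-fold higher and 38 were higher within each slide. These genes were called over the same slides, so being higher within each slide restates the calls and adds no support. Vav1, Cyth4 and Ptpn6 among them also rose in set 2, so they do not set these arrays apart from set 2. A swap with an siRNA group is argued against by Dmrt3, which was higher than in both siRNA sets by 0.864, 0.698 and 0.939 within slides (mean 0.834), although Dmrta2 differed from them by -0.04. Whether the probe lies outside the transfected sequence cannot be told apart from a plasmid that added no Dmrta2 transcript, because the files state neither the probe's place nor the plasmid's sequence. A lower transcription of the embryos' own Dmrta2 under added protein stays open, as untested.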

How the results depend on the processing

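The comparison of overexpression with both siRNA sets, normexp on the median spot signals, normexp with negative control spots and the tests with unnamed probes were chosen after the data were seen, and the others were planned. Signal over background limits the result: 67 of 104 gene results could be tested among genes well above background on all 12 arrays, and all 67 stayed past or short of the threshold there as before. Genes near background have only bounds, and 3 arrays per group limit every count. Counts of changed genes follow as siRNA average, set 1, set 2, overexpression, set 2 against set 1, overexpression against both siRNA sets, and shared by both sets (103, 36, 157, 42, 12, 330 and 16), and those not given were within 1.5 times. Where not stated otherwise, the cause of a shift was not tested.

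Median scaling gave 55 for the siRNA average, 15 for set 1, 50 for set 2, 1 for set 2 against set 1 and 5 shared. Of these, 80.0% were higher in set 1 (69.4% with the 75th percentile), 82.0% in set 2 (66.9%) and 5 of 5 shared genes (14 of 16), while the 1 gene of set 2 against set 1 was lower (7 of 12). Quantile normalization and the deposited values moved no count by over 1.5 times. Normexp with negative control spots gave 40 for the siRNA average, 57 for set 2, 27 for overexpression and 9 shared. With it, 28.6% of genes were higher in set 2 against set 1 (41.7%) and 9 of 9 shared genes, and Eda2r in set 1 reversed to -0.0671.

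Normexp on the median spot signals could not be fitted well on 3 arrays, where the background mean was placed at -1436 (overexpression replicate 1), -2182 (overexpression replicate 2) and -217.6 (set 1 replicate 2), against -5.385 to -12.67 on the others. It moved the median gene by 0.44 in overexpression, 0.39 in overexpression against both siRNA sets and 0.11 in set 1. With limma it called 9909 genes in overexpression and 10693 against both siRNA sets. It called 0 for the siRNA average, set 1, set 2, set 2 against set 1 and shared genes (193, 175, 227, 160 and 57 at an unadjusted p under 0.05), and in overexpression 67.3% of calls were higher (100% before). The values that reversed with it were Moxd1 in set 1 (0.18) and, against both siRNA sets, Prdm12 (1.36), Olig3 (1.25), Tac2 (0.12) and Tacr3 (1.07), along with the p53 response list in overexpression, whose median was 0.42 but whose members lay below other genes. Relative to the shift of 0.39, Tac2 alone stayed lower.

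Without a filter on dim probes the siRNA average gave 37, set 2 gave 26, 8 were shared, and set 2 against set 1 gave 0 with limma (1598 at an unadjusted p under 0.05). Genes well above background on all 12 arrays gave 26 for overexpression. With unnamed probes among the features, the siRNA average gave 55, set 2 gave 63 and set 2 against set 1 gave 0 with limma (1373 unadjusted). Fits of the compared groups alone gave 36 for the siRNA average and, with limma, 0 for set 1, set 2, set 2 against set 1 and shared genes (1251, 1825, 1090 and 481 unadjusted). These fits hold fewer arrays. A variance trend with robust moderation gave 31 for set 2 against set 1 and 1 gene opposite in siRNAs and overexpression. Array weights gave 1086, 421, 1405, 180, 307, 1207 and 216, and 7 opposite, with weights of 0.395 to 0.489 for the arrays of slide 2. A fold of at least 2 gave 49 for the siRNA average, 22 for set 1, 66 for set 2, 161 for overexpression against both siRNA sets and 8 shared. An adjusted p under 0.10 gave 246, 124, 357, 48 for set 2 against set 1, 577 against both siRNA sets, 54 shared and 2 opposite.

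The replicate block, here the slide, gave 233 for the siRNA average, 114 for set 1, 365 for set 2, 33 for set 2 against set 1, 527 for overexpression against both siRNA sets and 54 shared. Deviations from group means correlated above 0.1 in 16 of 18 pairs of arrays with the same number (0.0196 to 0.5993, other pairs -0.5159 to 0.2116), so the numbers, each of which is also a slide, were not taken to pair the samples. As a hint from the data, 12 of 12 arrays were closest to arrays of their own number. With this pairing 97 of 104 gene results and 33 of 39 list results kept their side of the threshold, 5 and 6 were no longer past it, and Dmrt3 passed in the siRNA average and in set 1. Within slide 2 the median of S and G2/M phase genes reversed to 0.0394 in the siRNA average and 0.263 in set 2, that of neurogenic genes to -0.0118, postmitotic neurons to -0.34 and erythroid genes to -0.26 in set 1, and that of interferon genes to -0.45 in overexpression. Within slide 3 that of neurogenic genes reversed to 0.10 in overexpression.

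Leaving out 1 array at a time gave 17 to 87 genes for the siRNA average, 4 to 83 for set 1, 10 to 143 for set 2, 18 to 55 for overexpression, 0 to 12 for set 2 against set 1 (limma, 1108 to 1534 at an unadjusted p under 0.05 where it was 0), 106 to 330 for overexpression against both siRNA sets, 2 to 19 shared and 0 to 1 opposite. The arrays behind these shifts are named beside each count. Dmrt3 in overexpression, not past the threshold with all arrays, ran from -0.237 to 0.121, above 0 without overexpression replicate 1 and without control replicate 3 (0.0891), and the median of neurogenic genes in overexpression from -0.238 to 0.0767, above 0 without control replicate 2. Over these 12 fits 760 of 1248 gene results and 408 of 468 list results kept their direction and side of the threshold.

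The other settings kept 82 (median scaling), 90 (quantile), 97 (deposited values), 58 (normexp with negative control spots), 65 (no filter), 97 (mean of all probes), 39 (groups alone), 101 (trend) and 100 (weights) of 104 gene results on their side of the threshold, and 39, 35, 37, 30, 32, 37, 35, 39 and 28 of 39 list results. With an estimated correlation 4 list results passed, and with fry 10.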

Other observations

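The comparison of overexpression with both siRNA sets, its list tests, the reading of single arrays and the restriction to splits balanced over slides were chosen after the result was seen, and the splits of the arrays were planned.

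The comparison of the arrays labelled Dmrta2 overexpression with both siRNA sets averaged leaves the control siRNAs out of the difference, and the Dmrta2 probe itself differed by -0.04 (97.5%, exact p = 0.893). Robo3, a receptor of axon guidance, was higher in overexpression 13.8-fold (3.79 ± 0.36 on the log2 scale, SE, n = 3 against 6; limma adjusted p = 0.00048), Cilp, measured on 1 of 6 siRNA arrays, by 3.78 ± 0.38 (6.48e-04, and 3.05 with the others at the lowest signal well above background), Ecel1 by 3.59 ± 0.33 (4.01e-04) and Fam20a by 3.55 ± 0.26, and Lamp5 at least 12.1-fold (9.63e-05). Tox was lower by 2.97 ± 0.37 (0.00278), Tacr3 by 2.79 ± 0.28 (7.47e-04), Olig3, measured on 1 of 3 overexpression arrays, by 3.78 ± 0.61 (0.012, and 2.49 with the others at that signal), and Prdm12, a transcription factor of sensory neurons, at least 6.15-fold (0.00278, with -0.34 on its other probe). Tac2, which encodes the ligand of the Tacr3 receptor, was lower by 3.17 ± 0.58 (0.0206). In all 330 genes differed, 200 higher and 130 lower, and 2044 at an unadjusted p under 0.05. Blocking on the slide gave 527, 315 of them among the 330. Leaving out 1 array gave 106 without overexpression replicate 3, 120 without overexpression replicate 2, 163 without overexpression replicate 1, 191 without set 1 replicate 3 and 214 without set 2 replicate 3. Lamp5, Robo3, Cilp, Ecel1, Prdm12, Tox and Tacr3 passed in all 12 such fits, Olig3 in 10 (0.075 without overexpression replicate 3) and Tac2 in 8 (0.116 without overexpression replicate 2). Within slides 1, 2 and 3 Robo3 differed by 3.44, 3.63 and 4.30.

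Among genes of the lists, named after their values were seen, Bmp2, a BMP ligand, was higher in overexpression by 2.06 ± 0.26 (limma adjusted p = 0.00329), Fgf15 by 1.11 ± 0.15 (0.00496), Msx1 by 0.76 ± 0.13 (0.0158), Spry1, an inhibitor of FGF signalling, by 0.88 ± 0.15 (0.0129), and Etv4 by 1.09 ± 0.23 (0.04). Ebf2 (1.39 ± 0.18, 0.00302) and Ebf1 (1.17 ± 0.16) of early neurons were higher too. Pax6, a regulator of the dorsal telencephalon, was lower by 1.52 ± 0.27 (0.0173, and 0.00538 with the slide as a block), Neurod4, measured on 1 of 3 overexpression arrays, by 1.64 ± 0.32 (0.026, and 1.42 with the others at the lowest signal well above background) and Ccng1 by 1.45 ± 0.18 (0.00295). These 10 genes passed with the slide as a block, and single arrays ended the calls of Msx1 (0.0983 without overexpression replicate 3), Spry1 (0.0679 without overexpression replicate 1), Etv4 (past in 3 of 12 fits, 0.178 without overexpression replicate 2), Pax6 (0.0795 without overexpression replicate 1) and Neurod4 (past in 6, 0.11 without overexpression replicate 2). The hem list had a median of 0.38 (camera adjusted p = 4.15e-04, and 0.369 with an estimated correlation), FGF 0.54 (4.15e-04, and 0.134), BMP 0.37 (4.15e-04, and 0.063), S and G2/M genes 0.28 (4.15e-04, and 0.562), surface ectoderm 0.78 (4.15e-04, and 0.116), Cajal-Retzius genes 0.43 (0.00227, and 0.369) and neurogenic genes -0.305 (0.0114, and 0.562). All 7 lists passed with the slide as a block (2.82e-05 to 0.0243) and in each fit that left out 1 array, and their slide medians kept their sign, with the hem list at 0.33, 0.23 and 0.54. Microglia genes (0.22, adjusted p = 0.282) and p53 genes (-0.04, 0.348) did not pass.

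Single arrays stood apart in genes of other cell types. Set 1 replicate 1 had Col1a1 at 0.39, Col3a1 at 0.22 and Ttr at 0.67 relative to the 75th percentile, against -5.55 to -1.87, -6.47 to -4.96 and -8.18 to -1.44 on the other 11 arrays. Without that array 75 genes changed in the siRNA average. Isg15 was at 1.09 in set 2 replicate 1 and at -0.10 in overexpression replicate 3, and at -2.51 to -0.63 on the other 10 arrays.

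Each count was set against other splits of the arrays into groups of the same sizes. Chance is argued against for the count of 103 genes in the siRNA average, where the highest other of 100 splits gave 36. The same holds for the count of 16 genes shared by both sets, where it gave 3. Neither is excluded, because splits that mix groups or slides carry those differences into the spread, which lowers their counts. Among the 28 of these splits whose controls held 1 array of each slide, as in the real one, the highest others gave 29 and 3. For the 330 genes of overexpression against both siRNA sets, 3 of 100 splits, the real one included, gave as many. The highest, 1193, set the 3 arrays of slide 2 against the others and points to a slide structure in the arrays. The highest other of the 34 splits balanced over slides gave 191, and the count blocked on the slide was 527. As this comparison was added after the data were seen, its splits do not exclude chance. Groups of 3 against 3 have 10 splits, too few for a share under 0.05, and the real split gave 36 genes in set 1, 157 in set 2 and 42 in overexpression, the highest other 0 in each (limma). For genes opposite in the siRNA average and overexpression the splits say nothing about chance, since all 100 give at least the 0 of the real split, and the highest other gave 0 (limma, 53 opposite at an unadjusted p under 0.05).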
